A study of Medicago truncatula with 72 samples.

How the data were processed

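RNA was measured by sequencing in *Medicago truncatula*, a legume that forms root nodules with the bacterium *Sinorhizobium meliloti*. Per the labels' protocols, seedlings were grown on medium with 1 µM of the ethylene synthesis inhibitor AVG. Their roots were spot-inoculated with about 1 µL of the bacterium (OD600 of 0.02, grown with 3 µM luteolin) or with a mock solution of Fahraeus medium and luteolin, and segments of 2 to 3 mm were taken 24 or 72 h later. The mutants were lsh1, lsh1lsh2 and noot1noot2 in the R108 background and nf-ya1 in the A17 background. The remaining libraries came from regenerated root structures that overexpressed LSH1 with LSH2, or NOOT1 with NOOT2.

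The deposited table holds unnormalised read counts per gene, per the file headers and its values, all of which are whole numbers. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with an Illumina TruSeq stranded mRNA kit. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.7.3a and counted with featureCounts. The genome build and the strand setting of the counting were not given in the sources used here, so reads of overlapping, antisense or closely similar genes could be shared or lost, and R108 reads may have been aligned to the sequence of another accession. The table has 50894 gene identifiers and 64 libraries. The labels describe 72 samples. The 8 wild-type R108 samples have no column in the table and were not analysed here, so 10 of the 23 planned comparisons, those that use R108, were not computed and 13 were. The 64 libraries fall into 18 groups of 3 or 4. For lsh1 mock 72 h the labels number the replicates 1, 3 and 4 and the table's columns 1 to 3, so a replicate number of that group is a column number and names no labelled sample.

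The table does not pair identifiers with names, and 0 of its identifiers matched the reference table of gene names (assembly MtrunA17r5.0-ANR). Symbols for 45 loci were therefore assigned from recall of the published literature before the data were examined, with no table at hand to check them. The reference table also lists 13 of these symbols, and 13 of the 13 lie there on the chromosome that the identifier names. The loci of LSH1 and LSH2 were recalled with less certainty and were accepted only after their counts in the overexpression libraries had been seen. A symbol in the text stands for the identifier printed with it at its first mention. The 45 loci fill 7 of 26 gene lists that were fixed before the data were examined. The other 19 lists, among them leghemoglobins, defence, cell cycle and the markers of other root cell types, could not be matched to identifiers and were not tested.

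All fits used R 4.3.3 with edgeR 4.0.16, and every p in the text comes from edgeR's quasi-likelihood F test unless another test is named. Libraries were scaled by TMM, low counts were removed with filterByExpr by group, the spread was estimated with robust empirical Bayes, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A group mean was fitted for each group. The 42 libraries of lsh1, lsh1lsh2 and noot1noot2 shared 1 fit (25090 genes tested), the 16 nf-ya1 libraries another (21484 genes) and the 6 overexpression libraries their own (24464 genes). The plan had placed the R108 libraries in the fit of the 42 libraries as well. Log2 fold changes are given with their standard error, taken as the absolute log2 fold change over the square root of F. Levels are CPM, counts scaled by the TMM-scaled library totals, as mean ± SD. A fold against a group with no counts is given as a lower bound, against a floor of 3 counts over the whole group. Against a group with 1 to 3 counts, the ratio of CPM is given with its exact 95% interval. Intervals and floors cover counting error only. For genes with so few mock counts the fitted log2 fold change depends on the prior count and is no bound.

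Gene lists were tested against all other genes with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Lists with 1 measured locus were not tested. List p-values were adjusted over the lists of a comparison. The named genes follow a rule fixed before the data were examined. They are NIN and the study's own genes (LSH1, LSH2, NOOT1, NOOT2, NFYA1) in every comparison, and the called members of each list with the largest fold changes, up to 3 per list in the lsh1lsh2 72 h response and the overexpression comparison and up to 2 elsewhere, there only for lists that pass their test. A further part of the rule needed product descriptions, which are lacking. The comparisons, their test, the threshold and the alternatives were likewise chosen before the data were examined. The alternatives were RLE size factors, no filter on low counts, a fit of only the libraries compared, the replicate number as a block, DESeq2 1.42.0, and leaving out each library in turn. Tests chosen after results were seen are named where they appear.

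Total counts, in megareads, were 13.5 to 28.8 per library (median 20.3) in the fit with 42 libraries, 8.75 to 13.9 (median 10.6) in nf-ya1 and 21.6 to 25.5 (median 23.5) in the overexpression set. The fits were tested on simulated counts with known changes. In the simulation of the lsh1lsh2 24 h response over 24594 genes, 83.6% of the genes changed 2-fold were recovered and 44.8% of those changed 1.5-fold. For the difference of the lsh1lsh2 and noot1noot2 responses at 24 h (24573 genes) the shares were 49.3% and 22.4%. Only better-counted genes were changed, and each gene had the same spread in every library. Libraries that stand apart from their group were thus not simulated, and the shares may overstate what the fits could detect. The labels do not say whether replicates were separate experiments or share plants, so the p-values measure the spread between these samples. They name no day or batch either, and each genotype's libraries would share any effect of when they were made.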

Results

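The data are read counts per gene for 64 libraries of *M. truncatula* root tissue. Root segments of lsh1, lsh1lsh2, noot1noot2 and nf-ya1 mutants were compared 24 and 72 h after inoculation with *S. meliloti* or a mock solution. LSH1 and LSH2 encode proteins of the ALOG family of organ boundary regulators. NOOT1 and NOOT2 encode BOP-type coactivators that keep the identity of the nodule, and NF-YA1 is a CCAAT-binding factor that acts downstream of NIN, the master regulator of nodulation. The groups held 4 libraries each in lsh1lsh2 at both times, in noot1noot2 at 24 h and in nf-ya1 at both times, and 3 each in lsh1 at both times and in noot1noot2 at 72 h. A pair of groups of 3 libraries came from regenerated root structures overexpressing LSH1 and LSH2, or NOOT1 and NOOT2. No wild-type or empty-vector libraries were analysed here, so each response is rhizobia against mock within 1 mutant, and no value says how a mutant differs from wild type.

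The study's own genes came first, as a check of the labels. In the overexpression libraries, LSH1 (Medtr1g069825) stood at 357 ± 23.1 CPM with LSH1LSH2 and at 0.857 ± 0.163 CPM with NOOT1NOOT2 (SD, n = 3 each), and LSH2 (Medtr7g097030) at 185 ± 20.2 and 0.384 ± 0.130 CPM. NOOT1 (Medtr7g090020) stood at 705 ± 28.3 CPM with NOOT1NOOT2 against 14.9 ± 5.54 with LSH1LSH2, and NOOT2 (Medtr1g051025) at 864 ± 37.9 against 4.40 ± 0.924. Every one of the 6 libraries lay on the side its label names, which for LSH1 and LSH2 is no check, since their loci were accepted from these counts. Transcripts of the mutated genes remained countable in the mutants. At 72 h with rhizobia, LSH1 reached 12.1 ± 6.19 CPM in lsh1lsh2 (n = 4), 30.2 ± 16.6 in lsh1 (n = 3), 92.1 ± 21.3 in noot1noot2 (n = 3) and 65.8 ± 16.8 in nf-ya1 (n = 4). LSH2 was at 1.26 ± 1.19 CPM in lsh1lsh2, 1.57 ± 1.07 in lsh1, 14.8 ± 3.61 in noot1noot2 and 8.24 ± 2.92 in nf-ya1, so its low level does not set lsh1lsh2 apart from lsh1. NOOT1 was at 12.8 ± 1.63 CPM in noot1noot2 and 28.7 ± 9.61 in lsh1lsh2, and NFYA1 (Medtr1g056530) at 45.5 ± 12.6 CPM in nf-ya1. Counts per gene do not show where in the gene the reads lie, so these levels do not check the lesions. In tests chosen after the levels were seen, LSH1 and LSH2 with rhizobia at 72 h were lower in lsh1lsh2 than in noot1noot2 by edgeR (log2 -2.93, SE 0.42, adjusted p = 8.23e-06, and log2 -3.55, SE 0.54, adjusted p = 1.52e-05), and NOOT1 was higher (log2 1.17, SE 0.41, adjusted p = 0.0377) while NOOT2 did not pass (log2 1.31, SE 0.68, adjusted p = 0.172). In lsh1, too, LSH1 (log2 -1.61, SE 0.44, adjusted p = 0.0273) and LSH2 (log2 -3.23, SE 0.60, adjusted p = 0.00273) were lower than in noot1noot2. Other groups differ from this: LSH1 was higher in lsh1lsh2 than in noot1noot2 in mock libraries at 72 h (1.45 against 0.0802 CPM; log2 3.96, SE 0.94, adjusted p = 0.00382), LSH2 in mock libraries at 24 h (log2 2.29, SE 0.76, adjusted p = 0.0251), and with rhizobia at 24 h LSH1 did not pass (log2 -0.78, SE 0.41, adjusted p = 0.158).

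**Figure D1:**
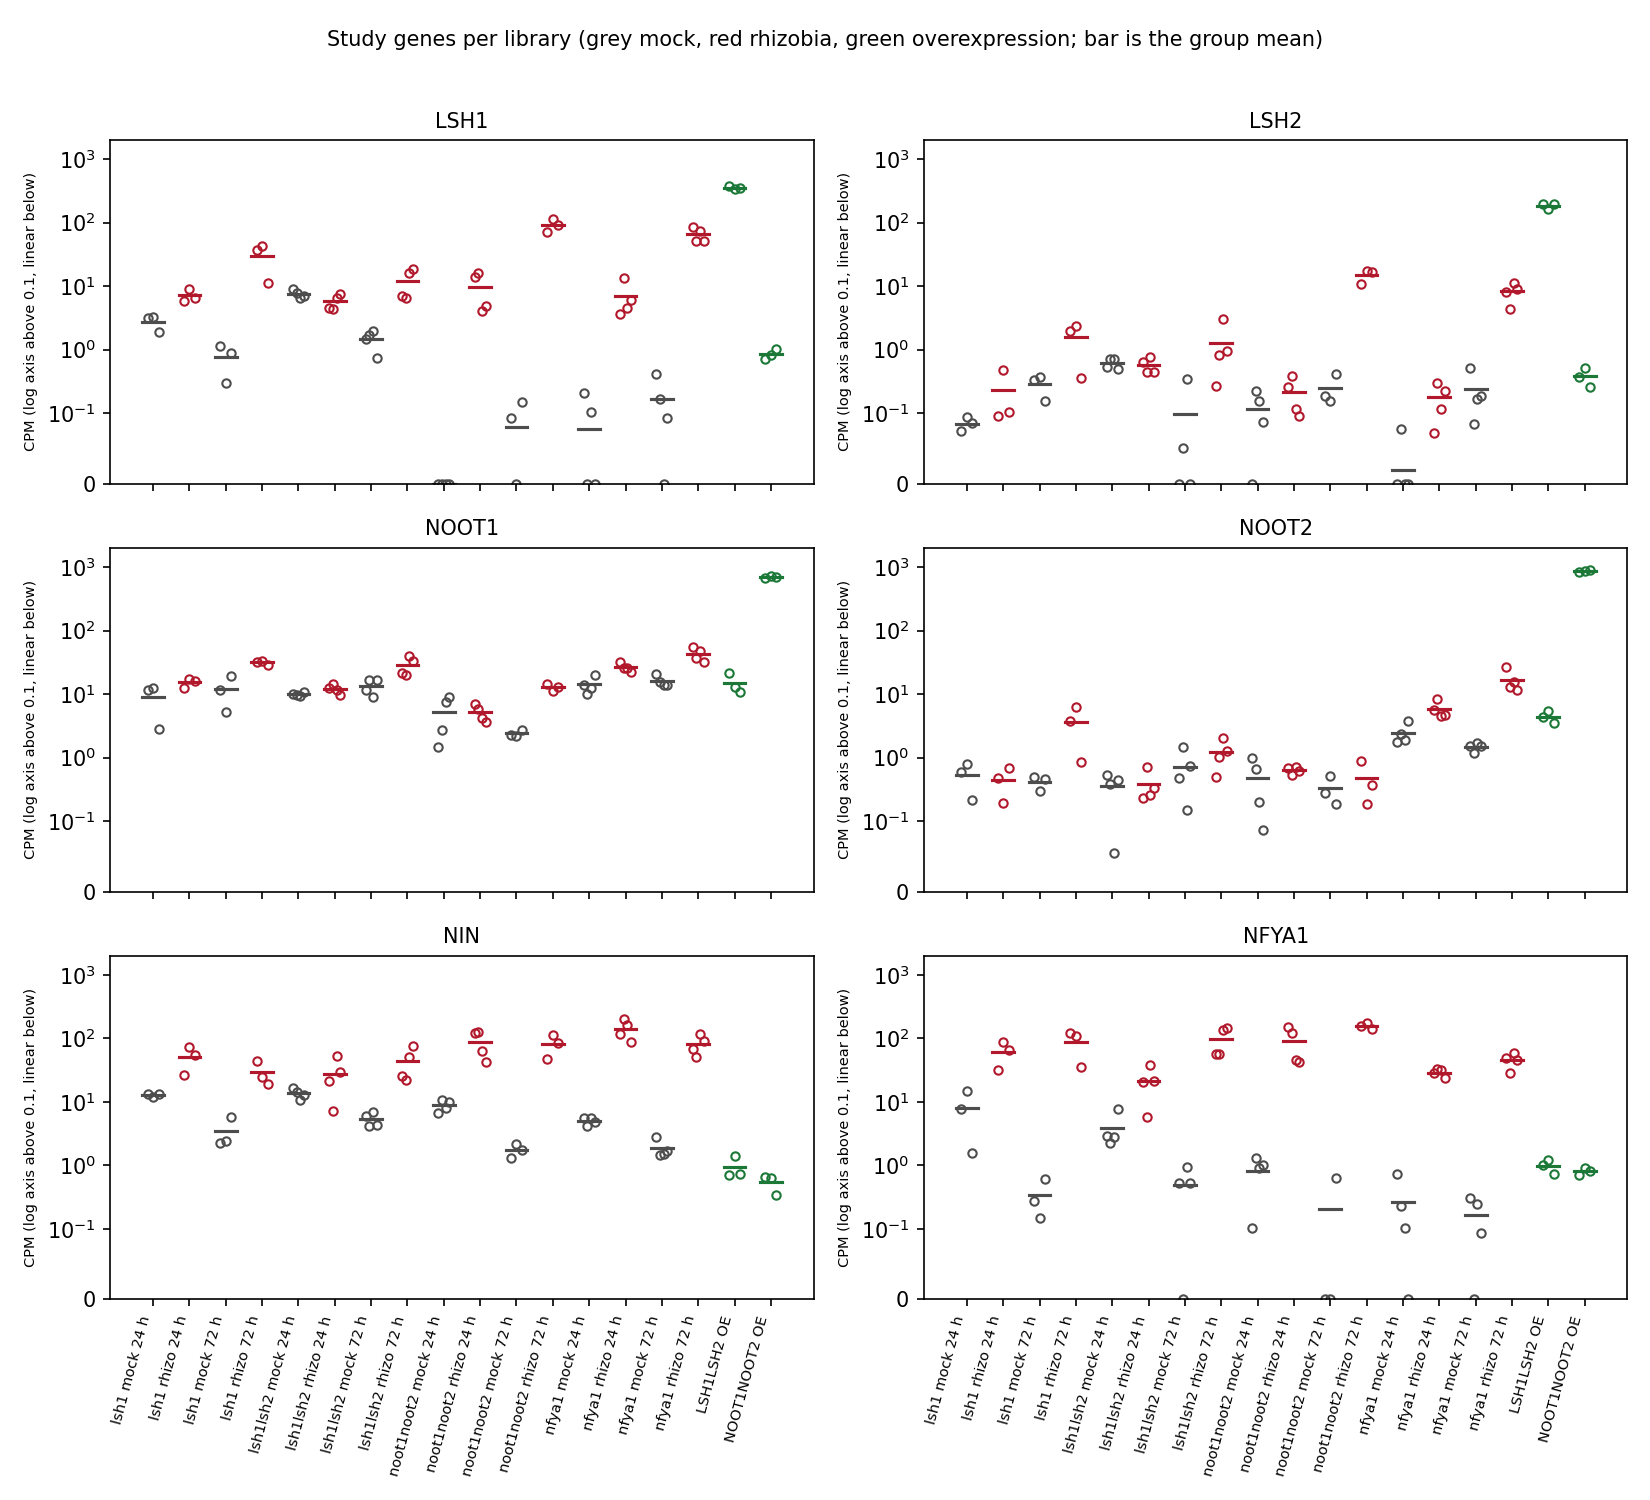
CPM per library (log axis above 0.1, linear below) of LSH1, LSH2, NOOT1, NOOT2, NIN and NFYA1, with mock libraries in grey, rhizobia in red, overexpression in green and a bar at each group mean. LSH1 stands at 335.7 to 382 CPM in the LSH1LSH2 libraries and at 0.706 to 1.03 CPM in the NOOT1NOOT2 libraries.

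The 72 h response of lsh1lsh2 asks which nodulation genes still follow inoculation when both LSH genes are mutated. There, 20 of the 25 measured loci of early symbiotic signalling and infection rose, 0 fell and 5 did not pass the test; 22 rose when adjusted over the list alone. NIN (Medtr5g099060) rose from 5.34 ± 1.35 to 43.4 ± 24.7 CPM (SD, n = 4 each; log2 3.02, SE 0.47, adjusted p = 4.12e-05). NFYA1 rose from 0.50 ± 0.385 to 98.8 ± 49 CPM (log2 7.60, SE 0.80), and NPL (Medtr3g086320), the pectate lyase that opens the cell wall for infection threads, from 0.0719 ± 0.114 to 9.09 ± 7.51 CPM (log2 6.84, SE 1.16). ENOD11 (Medtr3g415670), an early nodulin of the cell wall, was not counted in the 4 mock libraries and reached 121 ± 72.8 CPM, at least 3289-fold higher. LSH1 rose by a log2 of 3.05 (SE 0.46, adjusted p = 3.65e-05) and LSH2 by 3.60 (SE 0.74, adjusted p = 0.00138).

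Hormone, meristem and peptide loci also responded in lsh1lsh2 at 72 h. Both auxin synthesis loci rose, YUC2 (Medtr6g086870; log2 5.15, SE 0.55) and YUC8 (Medtr7g099330; log2 2.51, SE 0.29), 2 of 2 also when adjusted over the list alone. Of 7 root meristem and primordium loci, 4 rose, 0 fell and 3 did not pass (4 rose when adjusted over the list alone). Among them were the quiescent-centre regulator WOX5 (Medtr5g081990; log2 4.91, SE 0.73), the PLETHORA factor PLT3 (Medtr5g031880; log2 5.35, SE 0.80) and the lateral-root regulator LBD16 (Medtr7g096530; log2 2.04, SE 0.41). The peptide genes CLE12 (Medtr4g079630) and CLE13 (Medtr4g079610), which act in the control of nodule number, rose by log2 4.17 (SE 0.49) and 6.68 (SE 0.85), 2 of 2 also when adjusted over the list alone. Of 5 cytokinin loci 2 rose, 1 fell and 2 did not pass (the same counts when adjusted over the list alone): the receptor CRE1 (Medtr8g106150) rose by log2 0.47 (SE 0.13), the response regulator RR4 (Medtr5g036480) by 0.71 (SE 0.21), and the synthesis gene IPT3 (Medtr1g072540) fell by 0.55 on the log2 scale (SE 0.17). NOOT1 had a log2 of 1.08 (SE 0.37, adjusted p = 0.0591) and NOOT2 of 0.77 (SE 0.60, adjusted p = 0.444); 0 of these 2 passed, and 1 of 2 rose when adjusted over the list alone.

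By edgeR, 2224 of 25090 genes changed in lsh1lsh2 at 72 h, 1409 up and 815 down. The early symbiosis list (camera adjusted p = 1.68e-35), the auxin list (2.38e-10) and the peptide list (7.16e-09) ranked above other genes, and these calls held with an estimated correlation. The meristem list did so only with the preset correlation (adjusted p = 4.98e-05; adjusted p = 0.0584 with an estimated correlation), and the cytokinin list did not (adjusted p = 0.160). The count was 1470 when only these 8 libraries were fitted, 1093 without rhizobia replicate 3 and 999 without rhizobia replicate 4. The rhizobia libraries fall into pairs. Their chi-square per degree of freedom was 8.85 between replicates 1 and 2, 8.95 between 3 and 4, and 18.8 to 32.6 across the pairs. The 3 cytokinin calls were lost without rhizobia replicate 3, rhizobia replicate 4 or mock replicate 4, that of IPT3 also without mock replicate 2 and that of RR4 also without mock replicate 3. The log2 values were 0.41 to 0.58 for CRE1, 0.62 to 0.91 for RR4 and -0.65 to -0.35 for IPT3 over all libraries left out. That of IPT3 was also lost without the filter on low counts (-0.51) and with only these libraries (-0.53). NOOT1 was called with only these libraries (log2 1.11), by DESeq2 (1.09), and without rhizobia replicate 1 (1.24) or 2 (1.26), and LSH2 had a log2 of 5.86 without mock replicate 3.

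**Figure D2:**
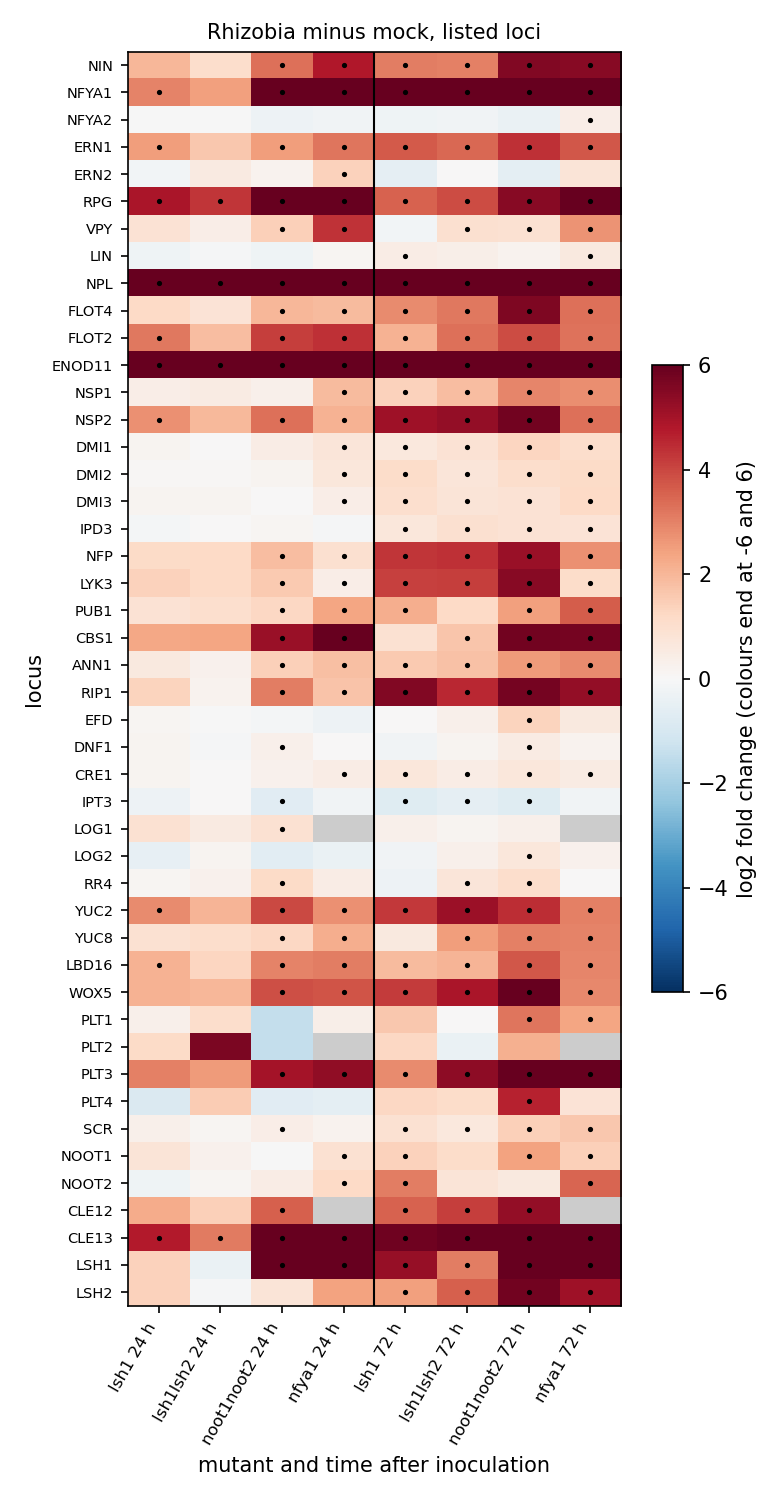
Fitted log2 fold change of rhizobia over mock for each listed locus (rows) in each mutant and time (columns), with colours ending at -6 and 6, a dot where adjusted p is under 0.05 and grey where a locus was not tested; values for loci with no mock counts are no bounds. In the early symbiosis list 3 loci rose in lsh1lsh2 at 24 h and 20 at 72 h, against 16 and 22 in noot1noot2.

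The lsh1 mutant is labelled for LSH1 alone, although its LSH2 level with rhizobia at 72 h was as low as given above. At 72 h, 20 of its 25 early symbiosis loci rose, 0 fell and 5 did not pass (20 rose when adjusted over the list alone). NIN rose from 3.49 ± 2.00 to 29.6 ± 13.5 CPM (SD, n = 3 each; log2 3.06, SE 0.57, adjusted p = 0.000464) and NFYA1 from 0.347 ± 0.245 to 88.5 ± 47.0 CPM (log2 7.88, SE 0.98). ENOD11 was at least 1903-fold above its uncounted mock level. Both organ boundary and identity loci rose, 2 of 2 also when adjusted over the list alone: NOOT1 by log2 1.37 (SE 0.43, adjusted p = 0.0216) and NOOT2 by 3.08 (SE 0.74, adjusted p = 0.00371). LSH1 rose by log2 5.22 (SE 0.59) and LSH2 by 2.48 (SE 0.74, adjusted p = 0.0158). YUC2 rose by log2 4.24 (SE 0.64) while YUC8 did not pass, so 1 of 2 auxin loci rose (1 when adjusted over the list alone). Of 7 meristem loci 4 rose, 0 fell and 3 did not pass (4 when adjusted over the list alone), with WOX5 at log2 4.21 (SE 0.85) and PLT3 at 2.84 (SE 0.80). CLE12 and CLE13 rose by log2 3.55 (SE 0.56) and 5.81 (SE 1.03), 2 of 2 also when adjusted over the list alone, and of 5 cytokinin loci 1 rose, 1 fell and 3 did not pass, likewise when adjusted over the list alone.

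By edgeR, 5455 genes changed in lsh1 at 72 h, 2411 up and 3044 down. In camera, the early symbiosis (adjusted p = 9.08e-18) and peptide (0.000243) lists passed and held with an estimated correlation. The auxin (0.00658), meristem (0.000280) and organ boundary (0.0239) lists did not, with adjusted p = 0.0641, adjusted p = 0.0665 and adjusted p = 0.0620 with an estimated correlation, and the cytokinin list passed neither (adjusted p = 0.859). The count fell to 146 when only these 6 libraries were fitted, and was 3433 without rhizobia replicate 1, 2429 without rhizobia replicate 2 and 1326 without mock replicate 2. Replicate numbers of these mock libraries are those of the table's columns, since the labels number the samples 1, 3 and 4. Mock replicate 2 held 13.47 megareads, 26085 genes with a count and 6.12% of its reads in the top 10 genes, against 18.31 and 18.76 megareads, 28352 and 28510 genes, and 4.08% and 3.95% in the other 2. Without rhizobia replicate 1 the calls of PLT3 (log2 2.44) and LSH2 (2.32) were lost, and without rhizobia replicate 2 those of NOOT1 (1.36) and LSH2 (2.11). Without mock replicate 2 the calls lost were those of PLT3 (2.30), NOOT1 (1.03) and LSH2 (2.69), and without mock replicate 3 that of LSH2 (2.21). With only these 6 libraries those of NOOT1 (1.41), NOOT2 (3.11) and PLT3 (2.88) were lost.

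The noot1noot2 mutant is labelled for the pair of genes that hold nodule identity. At 72 h, 22 of its 25 early symbiosis loci rose, 0 fell and 3 did not pass; adjusted over the list alone, 22 rose and 1 fell. NIN rose from 1.75 ± 0.443 to 83.0 ± 34.1 CPM (SD, n = 3 each; log2 5.57, SE 0.63, adjusted p = 6.49e-08) and NFYA1 from 0.210 ± 0.363 to 157 ± 16.3 CPM (log2 9.28, SE 1.01). ENOD11 was at least 2806-fold and NPL at least 352-fold above mock libraries without a count. LSH1 rose from 0.0802 ± 0.0748 to 92.1 ± 21.3 CPM (log2 9.94, SE 0.77, adjusted p = 3.77e-10) and LSH2 from 0.249 ± 0.137 to 14.8 ± 3.61 CPM (log2 5.81, SE 0.72). NOOT1 transcripts rose from 2.40 ± 0.30 to 12.8 ± 1.63 CPM (log2 2.41, SE 0.48), while NOOT2 had a log2 of 0.59 (SE 0.80, adjusted p = 0.588), so 1 of 2 organ boundary loci rose, likewise when adjusted over the list alone. Of 7 meristem loci 6 rose, 0 fell and 1 did not pass (6 when adjusted over the list alone), among them WOX5 (log2 6.75, SE 0.90) and PLT3 (log2 7.55, SE 1.05). YUC2 and YUC8 rose by log2 4.41 (SE 0.59) and 3.01 (SE 0.33), and CLE12 and CLE13 by 5.26 (SE 0.56) and 9.17 (SE 1.15), all 4 also when adjusted over their lists alone. Of 5 cytokinin loci 3 rose, 1 fell and 1 did not pass, likewise when adjusted over the list alone.

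By edgeR, 10237 genes changed in noot1noot2 at 72 h, 4821 up and 5416 down. Lists that passed camera and held with an estimated correlation were early symbiosis (adjusted p = 2.72e-19), meristem (1.45e-05), auxin (0.000199) and peptides (9.21e-05). The cytokinin (adjusted p = 0.149) and organ boundary (adjusted p = 0.149) lists did not pass. The fitted log2 of NFYA1 was 14.68 without mock replicate 3, the one mock library that had NFYA1 counts.

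The nf-ya1 libraries carry the A17 background and were fitted apart, so their values were not tested against the other mutants. At 72 h, 23 of 25 early symbiosis loci rose, 0 fell and 2 did not pass; adjusted over the list alone, all 25 rose. NIN rose from 1.85 ± 0.627 to 81.6 ± 28.3 CPM (SD, n = 4 each; log2 5.48, SE 0.35, adjusted p = 2.26e-08). NFYA1 transcripts rose from 0.163 ± 0.142 to 45.5 ± 12.6 CPM (log2 8.06, SE 0.43). ENOD11 was at least 4349-fold and NPL at least 318-fold above uncounted mock levels. LSH1 rose from 0.169 ± 0.176 to 65.8 ± 16.8 CPM (log2 8.59, SE 0.54) and LSH2 from 0.238 ± 0.189 to 8.24 ± 2.92 CPM (log2 5.10, SE 0.42). NOOT1 and NOOT2 rose by log2 1.43 (SE 0.20) and 3.49 (SE 0.31), 2 of 2 also when adjusted over the list alone. YUC2 and YUC8 rose by log2 3.04 (SE 0.33) and 2.97 (SE 0.50), and 5 of 6 meristem loci rose with 0 falling (5 when adjusted over the list alone), among them PLT3 (log2 6.20, SE 0.45) and LBD16 (log2 2.95, SE 0.23). CLE13 was the 1 peptide locus measured and rose, and of 4 cytokinin loci 1 rose, 0 fell and 3 did not pass. By edgeR, 8070 of 21484 genes changed, 4348 up and 3722 down. Tested with camera, the early symbiosis (adjusted p = 2.31e-46), meristem (1.06e-07), organ boundary (0.000738) and auxin (0.00345) lists passed and held with an estimated correlation. The cytokinin list did not pass (adjusted p = 0.461).

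The 24 h comparisons ask how far each mutant responds early. In nf-ya1 at 24 h, 21 of 25 early symbiosis loci rose, 0 fell and 4 did not pass (21 rose when adjusted over the list alone). NIN rose from 5.04 ± 0.708 to 142 ± 49.2 CPM (SD, n = 4 each; log2 4.83, SE 0.31, adjusted p = 2.33e-08), NFYA1 by log2 6.80 (SE 0.42), NOOT1 by 0.89 (SE 0.21) and NOOT2 by 1.21 (SE 0.31). ENOD11 was at least 1043-fold and NPL at least 550-fold above uncounted mock levels, and LSH1, with 3 mock counts, was 101-fold higher (95% counting interval 34.1 to 490.5). LSH2, with 1 mock count, had a ratio of 7.49 (0.962 to 337.5; adjusted p = 0.0955). YUC2 and YUC8 rose by log2 2.75 (SE 0.33) and 2.17 (SE 0.45). WOX5 and PLT3 rose by 3.79 (SE 0.41) and 5.32 (SE 0.39), in a meristem list of 6 with 3 risen, 0 fallen and 3 not past the test (3 when adjusted over the list alone). By edgeR, 8453 genes changed, 4558 up and 3895 down. The early symbiosis list (camera adjusted p = 3.94e-24) held with an estimated correlation. The meristem (0.000189) and auxin (0.0221) lists did not, both at adjusted p = 0.0669 with an estimated correlation, and the cytokinin (adjusted p = 0.602) and organ boundary (adjusted p = 0.137) lists did not pass.

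In noot1noot2 at 24 h, 16 of 25 early symbiosis loci rose, 0 fell and 9 did not pass; adjusted over the list alone, 17 rose and 1 fell. NIN rose from 8.86 ± 1.88 to 87.8 ± 41.8 CPM (SD, n = 4 each; log2 3.31, SE 0.46, adjusted p = 1.11e-05) and NFYA1 from 0.825 ± 0.509 to 90.3 ± 54.3 CPM (log2 6.73, SE 0.74). ENOD11 was at least 1122-fold above an uncounted mock level. LSH1 had no counts in the 4 mock libraries and reached 9.84 ± 6.26 CPM, at least 297-fold higher (adjusted p = 1.87e-07). LSH2 had a log2 of 0.79 (SE 0.87, adjusted p = 0.564), NOOT1 of -0.01 (SE 0.40) and NOOT2 of 0.44 (SE 0.65). YUC2 and YUC8 rose by log2 3.94 (SE 0.50) and 1.22 (SE 0.27), and CLE12 and CLE13 by 3.56 (SE 0.64) and 6.55 (SE 0.70), all 4 also when adjusted over their lists alone. Of 7 meristem loci 4 rose, 0 fell and 3 did not pass (4 when adjusted over the list alone), with WOX5 at log2 3.85 (SE 0.67) and PLT3 at 5.0 (SE 0.78). By edgeR, 6229 genes changed, 3717 up and 2512 down, and the count was 3255 without rhizobia replicate 1, 3763 without rhizobia replicate 2 and 3963 without mock replicate 3. The rhizobia libraries fall into 2 pairs, with a chi-square per degree of freedom of 8.80 between replicates 1 and 2, 6.76 between 3 and 4, and 37.6 to 54.9 across the pairs. NIN stood at 122.4 and 124.1 CPM in replicates 1 and 2 against 62.4 and 42.2 in 3 and 4, and NFYA1 at 150.3 and 122.3 against 45.6 and 43.1. By camera, the early symbiosis (adjusted p = 1.95e-12), auxin (0.000936) and peptide (0.000251) lists passed and held with an estimated correlation. The meristem list (0.0212) did not hold (adjusted p = 0.314 with an estimated correlation), and the cytokinin (adjusted p = 0.517) and organ boundary (adjusted p = 0.676) lists did not pass.

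The lsh1 response at 24 h was smaller in number. There, 7 of 25 early symbiosis loci rose, 0 fell and 18 did not pass, and 11 rose when adjusted over the list alone. NPL, with 1 count over the mock libraries, was 2074-fold higher (95% counting interval 372 to 81960; adjusted p = 0.000895) and CLE13 rose by log2 4.78 (SE 0.75, adjusted p = 0.00118), with calls that held without any of the 6 libraries. ENOD11 was at least 682-fold above its uncounted mock level (adjusted p = 0.00775). NFYA1 rose from 8.01 ± 6.52 to 62.2 ± 28.6 CPM (SD, n = 3 each; log2 2.97, SE 0.66, adjusted p = 0.0258), and YUC2 and LBD16 by log2 2.82 (SE 0.54) and 2.06 (SE 0.46). NIN went from 12.9 ± 0.853 to 51.6 ± 22.9 CPM without passing (log2 2.00, SE 0.51, adjusted p = 0.0762). LSH1 had a log2 of 1.38 (SE 0.50, adjusted p = 0.327), LSH2 of 1.38 (SE 1.04, adjusted p = 0.706), NOOT1 of 0.76 (SE 0.43, adjusted p = 0.573) and NOOT2 of -0.26 (SE 0.77, adjusted p = 0.946).

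By edgeR, 106 genes changed in lsh1 at 24 h, 102 up and 4 down; Medtr7g010860 (log2 -1.24) and Medtr2g023070 (log2 -0.66), chosen after their values were seen, are among the 4. Of the auxin loci 1 of 2 rose (2 adjusted over the list alone), of the meristem loci 1 of 7 (3), of the peptide loci 1 of 2 (2) and of the cytokinin loci 0 of 5 (1). Among the lists, early symbiosis (camera adjusted p = 1.04e-17), auxin (2.57e-05) and peptides (1.46e-06) held with an estimated correlation. The meristem list (0.000692) did not hold (adjusted p = 0.115 with an estimated correlation), and the cytokinin (adjusted p = 0.573) and organ boundary (adjusted p = 0.400) lists did not pass. The count ran from 20 (without mock replicate 3) to 266 (without rhizobia replicate 1) over the 6 libraries left out, each moving it by over 1.5 times. These 2 libraries stand apart from their groups, with a chi-square per degree of freedom of 39.9 and 44.1 for mock replicate 3 (4.80 between the other 2) and 14.1 and 22.1 for rhizobia replicate 1 (4.50 between the other 2). NFYA1 was at 1.56 CPM in that mock library against 7.87 and 14.6, and NIN at 27.0 CPM in that rhizobia library against 55.6 and 72.1. The count was 15 with only these libraries and 169 by DESeq2. The call of ENOD11 was lost without any of the 3 mock libraries (log2 12.22 to 12.24). Those of NFYA1, YUC2 and LBD16 were lost without rhizobia replicate 2, mock replicate 1 or mock replicate 3. Without rhizobia replicate 3 those of NFYA1 and LBD16 were lost, and without mock replicate 2 that of LBD16. Over all libraries left out their log2 values were 2.47 to 3.70, 2.31 to 3.20 and 1.87 to 2.37. With only these 6 libraries the calls of ENOD11 (12.31), NFYA1 (2.97), YUC2 (2.82), LBD16 (2.07) and CLE13 (4.79) were lost, without the filter those of NFYA1 (2.96) and LBD16 (2.05), and by DESeq2 that of NFYA1 (2.94). NIN was called by DESeq2 (log2 1.98) and without rhizobia replicate 1 (2.30).

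In lsh1lsh2 at 24 h, 3 of 25 early symbiosis loci rose, 0 fell and 22 did not pass, and 12 rose when adjusted over the list alone. NPL and ENOD11 had no counts in the 4 mock libraries and reached 9.62 ± 10.3 and 9.87 ± 9.52 CPM (SD, n = 4), at least 242-fold (adjusted p = 0.00398) and at least 248-fold higher (adjusted p = 0.0439). CLE13 rose from 3.60 ± 1.55 to 31.2 ± 25.5 CPM (log2 3.11, SE 0.62, adjusted p = 0.0196), 1 of 2 peptide loci (2 adjusted over the list alone). NIN went from 13.6 ± 2.41 to 27.9 ± 19.3 CPM (log2 1.04, SE 0.44, adjusted p = 0.521) and NFYA1 from 3.95 ± 2.55 to 21.6 ± 13.4 CPM (log2 2.44, SE 0.61, adjusted p = 0.0868), and neither passed. LSH1 had a log2 of -0.38 (SE 0.41), LSH2 of -0.09 (SE 0.62), NOOT1 of 0.26 (SE 0.38) and NOOT2 of 0.11 (SE 0.73). The auxin loci did not pass over all genes (0 of 2, and 2 of 2 adjusted over the list alone), nor did the meristem loci (0 of 7, and 2 adjusted over the list alone) or the cytokinin loci (0 of 5, and 0).

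By edgeR, 60 genes changed in lsh1lsh2 at 24 h, 39 up and 21 down, and 1975 had an unadjusted p under 0.05. Rhizobia replicate 2 stands apart from its group: its top 10 genes held 10.47% of its reads, against 5.51% to 6.07%, and its chi-square per degree of freedom was 55.4 to 74.9 against the other 3, which lay at 7.94 to 12.6 among themselves. The early symbiosis (camera adjusted p = 7.33e-16), auxin (6.82e-06), meristem (1.34e-05) and peptide (0.000138) lists ranked above other genes and held with an estimated correlation; the cytokinin (adjusted p = 0.173) and organ boundary (adjusted p = 0.588) lists did not pass. The count was 26 without the filter on low counts, 187 by DESeq2, 26 without rhizobia replicate 3, and 10, 14, 38 and 37 without mock replicate 1, 2, 3 and 4. The call of ENOD11 was kept only without rhizobia replicate 1 or 2 (log2 9.98 to 11.09 over all libraries left out), that of CLE13 was lost without rhizobia replicate 3 or mock replicate 1, 2 or 3 (2.45 to 3.47), and NFYA1 was called without rhizobia replicate 2 (2.75). NIN was not called with any library left out, with log2 0.51 (without rhizobia replicate 3) to 1.35. With only these 8 libraries 78 genes were called, 8 of them among the 60, and the calls of NPL (10.48), ENOD11 (10.52) and CLE13 (3.11) were lost, and without the filter those of ENOD11 (10.69) and CLE13 (3.10).

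**Figure D3:**
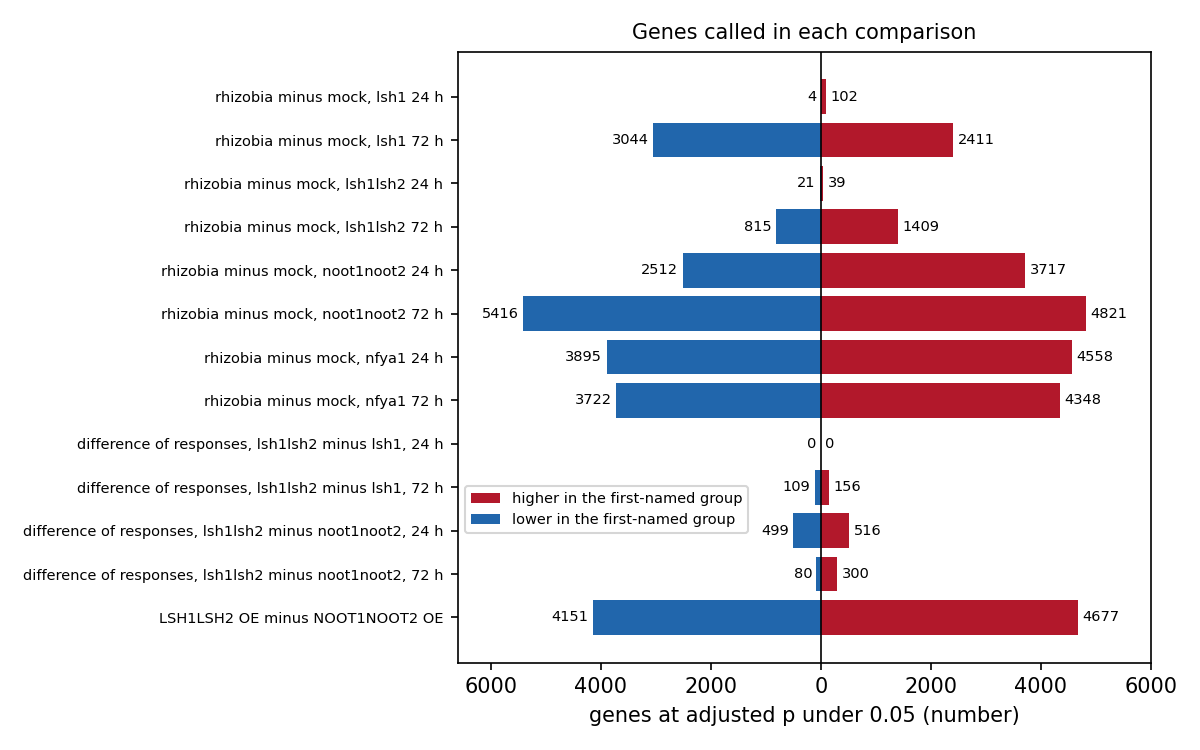
Number of genes at an adjusted p under 0.05 in each comparison, with genes higher in the first-named group to the right and lower ones to the left. At 24 h the bars stand at 102 and 4 in lsh1, 39 and 21 in lsh1lsh2, 3717 and 2512 in noot1noot2 and 4558 and 3895 in nf-ya1.

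Differences of responses ask whether a gene followed inoculation differently in lsh1lsh2 than in lsh1. At 24 h, edgeR called 0 genes, against 1084 at an unadjusted p under 0.05, 2 with only the libraries compared and 6 by DESeq2. None of the listed loci passed, also when adjusted over each list alone, and NIN differed by log2 -0.96 (SE 0.66, adjusted p = 0.961) and LSH1 by -1.76 (SE 0.65, adjusted p = 0.961). At 72 h, YUC8 responded more in lsh1lsh2 than in lsh1 (log2 1.91, SE 0.43, adjusted p = 0.0321), 1 of 2 auxin loci, likewise when adjusted over the list alone; it lies outside the rule and was chosen after its value was seen. The responses of NIN (log2 -0.04, SE 0.71), NFYA1 (-0.28, SE 1.60), NOOT1 (-0.29, SE 0.56), NOOT2 (-2.31, SE 0.95, adjusted p = 0.163), LSH1 (-2.17, SE 0.77, adjusted p = 0.113) and LSH2 (1.12, SE 1.11) did not pass. Of the 25 early symbiosis loci 0 passed, also when adjusted over the list alone, and 0 of the 6 lists tested passed at either time. Adjusted over their lists alone at 72 h, 1 of 2 organ boundary loci responded less in lsh1lsh2 and 1 of 5 cytokinin loci had a higher value. At 72 h edgeR called 265 genes, 156 with a higher and 109 with a lower log2 response in lsh1lsh2, where a higher value can also be a weaker fall. The count was 84 without the filter, 14 with only the libraries compared, 1210 by DESeq2, and 20 (without lsh1 rhizobia replicate 2) to 2665 (without lsh1 mock replicate 3) with 1 library left out. There, only lsh1 rhizobia replicate 1 (307) and lsh1lsh2 mock replicate 1 (288) moved it by less than 1.5 times. The call of YUC8 was lost without 6 of the 14 libraries, lsh1 rhizobia replicates 2 and 3, lsh1 mock replicate 2, lsh1lsh2 rhizobia replicate 4 and lsh1lsh2 mock replicates 3 and 4 (log2 1.64 to 2.18 over all 14), and with only the libraries compared (1.89). LSH1 was called by DESeq2 (log2 -2.22). LSH2, still not called, had a log2 of 3.335 without lsh1lsh2 mock replicate 3 and of 0.224 without lsh1lsh2 rhizobia replicate 3.

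Against noot1noot2, 4 loci named by the rule besides LSH1 responded less in lsh1lsh2 at 24 h. These were NIN (log2 -2.27, SE 0.62, adjusted p = 0.0363), NFYA1 (log2 -4.29, SE 0.95, adjusted p = 0.0233), the peroxidase RIP1 (Medtr5g074860; log2 -2.84, SE 0.78, adjusted p = 0.0376) and CLE13 (log2 -3.44, SE 0.89, adjusted p = 0.0322). The early symbiosis list had 0 higher, 3 lower and 22 not past the test (7 lower when adjusted over the list alone), and the peptide list 1 lower of 2 (2 adjusted over the list alone). DNF1 (Medtr3g027890), a signal peptidase subunit of the nodule and chosen after its value was seen, differed by log2 -0.42 (SE 0.12, adjusted p = 0.0493). LSH1 responded in noot1noot2 by at least 297-fold and in lsh1lsh2 by a log2 of -0.38, and the difference passed (adjusted p = 9.75e-06). Part of this lies in the mocks: in tests chosen after the levels were seen, LSH1 stood at 7.48 CPM in lsh1lsh2 mock and was not counted in noot1noot2 mock (adjusted p = 3.63e-08), and NFYA1 was higher in lsh1lsh2 mock (log2 2.23, SE 0.80, adjusted p = 0.0397), while NIN did not pass there (log2 0.62, SE 0.45, adjusted p = 0.350). With rhizobia both NFYA1 (21.6 against 90.3 CPM; log2 -2.06, SE 0.54, adjusted p = 0.00523) and NIN (log2 -1.65, SE 0.43, adjusted p = 0.00467) were lower in lsh1lsh2. NOOT1, NOOT2 and LSH2 differed by log2 0.27 (SE 0.55), -0.33 (SE 0.98) and -0.88 (SE 1.07), and did not pass.

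By edgeR, 1015 genes differed at 24 h, 516 with a higher and 499 with a lower log2 response in lsh1lsh2, where a higher value can stand for a weaker fall than in noot1noot2. The early symbiosis (camera adjusted p = 0.00685) and peptide (0.0349) lists ranked below other genes only with the preset correlation (adjusted p = 0.728 and adjusted p = 0.272 with an estimated correlation), and the other 4 lists did not pass; the meristem list had a median of -0.26 and a mean of 0.78. The count was 416 without the filter, 2260 by DESeq2, and 5 (without noot1noot2 mock replicate 3) to 2762 (without noot1noot2 rhizobia replicate 3) with 1 library left out. It was 8 and 9 without noot1noot2 rhizobia replicates 1 and 2, the pair with the higher NIN and NFYA1. Without lsh1lsh2 rhizobia replicate 2, the library that stands apart from its group, the count was 28. Only lsh1lsh2 mock replicate 4 (751) and noot1noot2 mock replicates 2 (1335) and 4 (703) moved it by less than 1.5 times. The calls of NIN, NFYA1, RIP1, CLE13 and DNF1 were lost without lsh1lsh2 rhizobia replicate 1 or 2, noot1noot2 rhizobia replicate 1 or 2, or noot1noot2 mock replicate 3. All but that of NFYA1 were also lost without lsh1lsh2 rhizobia replicate 4, lsh1lsh2 mock replicate 1 or 2, or noot1noot2 mock replicate 1. Over all 16 libraries left out, log2 ran from -2.80 to -1.95 for NIN, -4.74 to -3.73 for NFYA1, -3.18 to -2.55 for RIP1, -4.11 to -3.07 for CLE13 and -0.50 to -0.34 for DNF1. That of RIP1 was also lost without lsh1lsh2 mock replicate 3, that of CLE13 without lsh1lsh2 mock replicate 4, and that of DNF1 without lsh1lsh2 mock replicate 3 or 4 or noot1noot2 mock replicate 4, while that of LSH1 was kept without any of the 16. Without the filter the calls of NIN (-2.30), RIP1 (-2.87), CLE13 (-3.47) and DNF1 (-0.44) were lost, and with only the libraries compared those of NIN (-2.30) and CLE13 (-3.47).

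At 72 h the same difference was called for fewer loci. CBS1 (Medtr6g052300), a CBS-domain gene of infection, responded less in lsh1lsh2 than in noot1noot2 (log2 -4.11, SE 1.04, adjusted p = 0.0343), as did EFD (Medtr4g008860), an ERF-type factor of nodule differentiation (log2 -1.01, SE 0.25, adjusted p = 0.0312), and LSH1 (log2 -6.89, SE 0.97, adjusted p = 0.000417). NIN had a log2 of -2.55 (SE 0.75, adjusted p = 0.0718), NFYA1 of -1.68 (SE 1.62), LSH2 of -2.20 (SE 1.20, adjusted p = 0.366), NOOT1 of -1.33 (SE 0.60, adjusted p = 0.263) and NOOT2 of 0.18 (SE 1.04), and these did not pass. By edgeR tests chosen after the levels were seen, part of the LSH1 difference lies in the mocks. LSH1 was higher in lsh1lsh2 mock (1.45 against 0.0802 CPM, log2 3.96, SE 0.94, adjusted p = 0.00382) and lower with rhizobia (log2 -2.93, SE 0.42, adjusted p = 8.23e-06). NIN stood at 5.34 against 1.75 CPM in mock (log2 1.61, SE 0.60, adjusted p = 0.0567). With rhizobia NIN had a log2 of -0.94 (SE 0.445, adjusted p = 0.1345), and neither NIN test passed. The early symbiosis list had 0 higher, 2 lower and 23 not past the test (3 lower when adjusted over the list alone), and the meristem list 0 of 7 (3 lower when adjusted over the list alone). Both lists ranked below other genes with the preset correlation (camera adjusted p = 2.22e-05 and 5.0e-05) and not with an estimated one (adjusted p = 0.202 and adjusted p = 0.188 with an estimated correlation), and the other 4 lists did not pass.

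By edgeR, 380 genes differed at 72 h, 300 with a higher and 80 with a lower log2 response in lsh1lsh2, where again a higher value can be a weaker fall. The count was 155 with only the libraries compared, 786 by DESeq2, and 72 (without noot1noot2 rhizobia replicate 2) to 803 (without lsh1lsh2 rhizobia replicate 4) with 1 library left out. There, only lsh1lsh2 rhizobia replicate 3 (347) and lsh1lsh2 mock replicates 1 (394), 2 (256) and 3 (323) moved it by less than 1.5 times. The calls of CBS1 (log2 -6.69 to -3.48 over all 14 libraries) and EFD (-1.15 to -0.91) were lost without lsh1lsh2 rhizobia replicate 2, lsh1lsh2 mock replicate 4, noot1noot2 rhizobia replicate 2 or 3, or noot1noot2 mock replicate 1 or 3. That of CBS1 was also lost without lsh1lsh2 rhizobia replicate 1 or lsh1lsh2 mock replicate 1. With only the libraries compared the calls of CBS1 (-4.16) and EFD (-1.06) were lost as well, and CBS1 had a log2 of -6.69 without noot1noot2 mock replicate 2. NIN was called by DESeq2 (log2 -2.57) and without lsh1lsh2 rhizobia replicate 4 (-2.98) or noot1noot2 rhizobia replicate 1 (-2.87), LSH2 had a log2 of 0.01 without lsh1lsh2 mock replicate 3, and LSH1 was kept without any of the 14. NFYA1, still not called, had a log2 of -7.08 without noot1noot2 mock replicate 3.

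The overexpression comparison asks how regenerated root structures with LSH1 and LSH2 differ from those with NOOT1 and NOOT2. The infection loci VPY and FLOT4 were lower with LSH1LSH2. Vapyrin VPY (Medtr6g027840) stood at 1.04 ± 0.167 against 2.50 ± 0.312 CPM (SD, n = 3 each; log2 -1.26, SE 0.22, adjusted p = 0.00342), and the flotillin FLOT4 (Medtr3g106430) at 5.46 ± 0.462 against 11.5 ± 2.25 CPM (log2 -1.07, SE 0.16, adjusted p = 0.00192). RIP1 was higher (log2 1.08, SE 0.26, adjusted p = 0.0167), and of 22 early symbiosis loci measured 2 were higher, 5 lower and 15 did not pass, likewise when adjusted over the list alone. Of 7 meristem loci 2 were higher, 3 lower and 2 did not pass, likewise when adjusted over the list alone. LBD16 (log2 1.11, SE 0.18, adjusted p = 0.00247) and the endodermal regulator SCR (Medtr7g074650; log2 0.64, SE 0.14, adjusted p = 0.0103) were higher, and PLT2 (Medtr4g065370; log2 -0.96, SE 0.18, adjusted p = 0.00475) was lower. CRE1 and RR4 were higher by log2 0.23 (SE 0.07, adjusted p = 0.0338) and 0.56 (SE 0.17, adjusted p = 0.0331), 2 of 5 cytokinin loci with 0 lower (2 higher and 1 lower when adjusted over the list alone). The auxin loci did not pass (0 of 2, likewise when adjusted over the list alone). NIN stood at 0.948 ± 0.389 against 0.546 ± 0.176 CPM (log2 0.81, SE 0.39, adjusted p = 0.142) and NFYA1 at 0.987 ± 0.235 against 0.812 ± 0.105 CPM (log2 0.28, SE 0.28, adjusted p = 0.470), in tissue without rhizobia in its labels.

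By edgeR, 8828 of 24464 genes differed between the overexpression sets, 4677 higher and 4151 lower with LSH1LSH2. LSH1 and LSH2 had the lowest p-values (rank 1 and rank 2), NOOT2 had rank 3 and NOOT1 rank 43. The ranks of LSH1 and LSH2 are no check, since their loci were accepted after these counts had been seen. The organ boundary list here consists of the transgenes NOOT1 (log2 -5.57, SE 0.26) and NOOT2 (log2 -7.61, SE 0.15), so the constructs fix its outcome. The early symbiosis (adjusted p = 0.456), meristem (adjusted p = 0.826), auxin (adjusted p = 0.826) and cytokinin (adjusted p = 0.826) lists did not pass; the meristem list had a median of -0.05 and a mean of 0.02. The count was 5528 without NOOT1NOOT2 replicate 1. The call of RIP1 was lost without LSH1LSH2 replicate 1 (log2 0.96) or 2 (0.99), that of CRE1 was kept only without LSH1LSH2 replicate 3 or NOOT1NOOT2 replicate 2 (0.17 to 0.29 over all 6) and that of RR4 only without LSH1LSH2 replicate 1 (0.46 to 0.75). Without the filter on low counts that of RIP1 (1.08) was lost too.

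**Figure D4:**
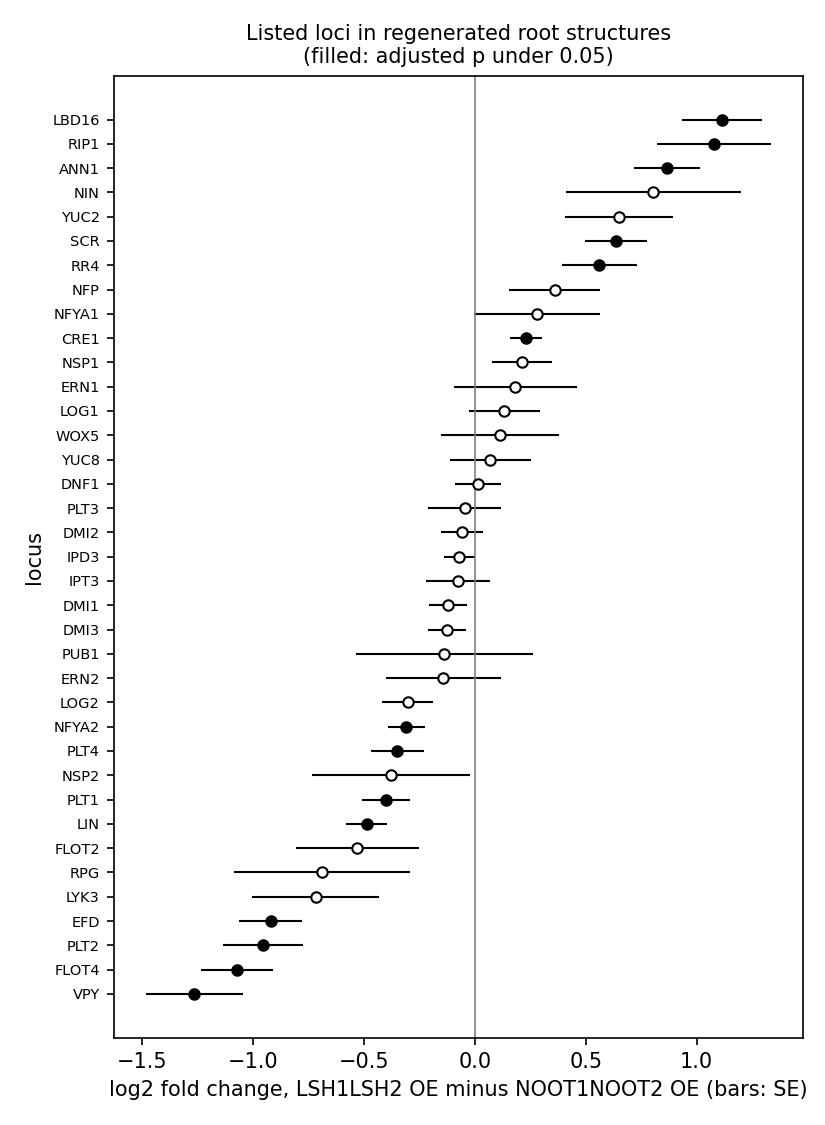
Log2 fold change with SE of each listed locus, LSH1LSH2 against NOOT1NOOT2 overexpression (n = 3 libraries each), without the transgenes, filled where adjusted p is under 0.05. VPY lies at -1.26 and LBD16 at 1.11.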

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

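The tests of depth, of LSH1 and ENOD11 in mock libraries of the dispersion and of the splits of the 2 lsh1 responses were chosen only after the results they concern had been seen. The other splits were not. The ratios of median responses weigh a pattern and a library that the results had already shown, so they were not fixed before the data were examined.

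A test of the difference itself singled out 3 comparisons between mutants. Between lsh1lsh2 and lsh1 at 72 h, 265 genes responded differently, YUC8 among them (log2 1.91). Between lsh1lsh2 and noot1noot2 at 24 h, 1015 genes did, with NIN at log2 -2.27, NFYA1 at -4.29, RIP1 at -2.84, DNF1 at -0.42, CLE13 at -3.44 and LSH1 at -11.08, a fitted value that is no bound, as LSH1 had no noot1noot2 mock counts. At 72 h, 380 genes did, with CBS1 at log2 -4.11, EFD at -1.01 and LSH1 at -6.89. Errors, p-values and the libraries that carry these calls stand in the report. With 1 library left out, the 3 counts ran from 20 to 2665, from 5 to 2762 and from 72 to 803.

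Single libraries far from the others of their group of 4 were NFYA1 in lsh1lsh2 mock 24 h replicate 4 (7.75 CPM against 2.26 to 2.95), LSH2 in lsh1lsh2 mock 72 h replicate 3 (0.346 CPM against 0 to 0.0507) and LSH2 in nf-ya1 mock 24 h replicate 2 (0.077 CPM, 1 count, against 0). These are 3 of the 70 values examined, which were library totals, NIN and the study's own genes in groups of 4. Chance would flag about 1 in 20, here 3.5, if the values were normally distributed, which need not hold for counts near 0. The screen covers no other genes. It did not flag lsh1lsh2 rhizobia 24 h replicate 2, which stands apart from its group by chi-square.

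Splits of the same libraries into other groups were refitted with only the libraries compared. For the responses of lsh1lsh2, only the real split of 35 was as large at 24 h (78 genes, 1 at most in the other splits) and 72 h (1470, at most 13). Of the 78, only 8 are among the 60 of the joint fit, so this says little of the others. The same held for noot1noot2 at 24 h (4341, at most 1) and for nf-ya1 at 24 h (8792, at most 0) and 72 h (6344, at most 27). A share of 1 in 35 is the lowest these splits can give and was not adjusted over the comparisons. It makes chance unlikely as the source of each count but does not exclude it. For the difference between lsh1lsh2 and noot1noot2 at 24 h, only the real split of 50 was as large (1384, at most 1). The other splits mix genotypes whose levels differ in 5782 genes in mock and 6690 with rhizobia by edgeR. That raises the spread within their groups and leaves few genes to call, so they cannot decide on chance for this difference. The splits are too few in lsh1 at 24 h (15, at most 2) and 72 h (146, at most 0), in noot1noot2 at 72 h (9950, at most 0) and for overexpression (8828, at most 0), each with 1 of 10 as large.

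For the differences between lsh1lsh2 and lsh1, 2 of 50 splits were as large at 24 h (2 genes, at most 4 in the others) and 2 of 50 at 72 h (14, at most 52), shares under 0.05. Since another split called more genes than the real one at both times, these counts are no firm ground for excluding chance, and at 24 h the joint fit called 0 genes by edgeR (1084 at an unadjusted p under 0.05, 6 by DESeq2). The split with 52 genes kept the rhizobia libraries in place and moved 4 mock libraries between the genotypes. With the mocks mixed, its contrast also takes in differences of level between the genotypes with rhizobia, which could raise its count. How much of the count this accounts for was not tested, nor was it told apart from chance. Splits of this kind cannot decide on chance. For lsh1lsh2 against noot1noot2 at 72 h, 3 of 50 splits were as large (155, at most 260). These splits, too, mix genotypes whose levels differ, in 4696 genes in mock and 5191 with rhizobia by edgeR. The split with 260 genes again kept the rhizobia libraries in place and moved mock libraries, so it takes in such level differences. The splits thus cannot decide on chance, which is not excluded for that difference.

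The first pattern weighed is the smaller response of lsh1lsh2 than of noot1noot2 at 24 h. The lsh1lsh2 libraries held a mean of 19.11 megareads, below the 23.01 of noot1noot2 but 1.69 times the 11.31 of nf-ya1. In nf-ya1, another background that was fitted apart, 8453 genes were called, so the tables argue against lower depth alone. They argue against equal fold changes hidden by a larger spread: over 8210 genes called in nf-ya1 at 24 h, the median log2 in the nf-ya1 direction was 0.0577 in lsh1lsh2 and 0.363 in noot1noot2, a ratio of 0.159 (0.0658 to 0.239 with any 1 library left out). The same ratio for lsh1 over noot1noot2 was 0.514. Its size holds for these genes only. The early symbiosis list had a median log2 of 0.835 in lsh1lsh2 and 1.548 in noot1noot2, and the meristem list went the other way, 1.519 against 0.398. The tables argue against rhizobia replicate 2 of lsh1lsh2 alone as the source of the smaller median response over the genes called in nf-ya1, since the ratio without it was 0.239 (0.144 to 0.306 with 1 more left out). The count of genes that differ does lean on that library, with 28 by edgeR without it against 1015 with it. What stays open is the part of noot1noot2 rhizobia replicates 1 and 2, which stand apart from 3 and 4 and were not left out together, an effect of the day or of inoculation, which the labels leave confounded with genotype, and an effect of the LSH genes, which may be the reason but is a hypothesis without wild-type libraries.

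The second pattern is LSH1 in lsh1lsh2 mock libraries at 24 h, 6.55 to 8.85 CPM where noot1noot2 had no count. LSH1 was also higher than in noot1noot2 in lsh1 mock libraries at 24 h (2.75 CPM against no count, adjusted p = 0.000105) and 72 h (0.773 against 0.0802 CPM, adjusted p = 0.0350) and in lsh1lsh2 mock libraries at 72 h (1.45 CPM, adjusted p = 0.00382). By the lowest ENOD11 to LSH1 ratio of noot1noot2 with rhizobia (3.35), a rhizobia response in the lsh1lsh2 mocks at 24 h would need ENOD11 at 21.9 CPM or more. The inoculated lsh1lsh2 libraries had less ENOD11 than that on average, so this level may be too high for lsh1lsh2. ENOD11 was not counted in these mocks at all (floor of 3 counts per library, 0.166 CPM), which argues against that explanation. An altered LSH1 transcript in the mutants stays open and was not tested, as do reads of a similar gene.

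The third pattern is the lsh1 response at 72 h, with 5455 genes in the joint fit and 146 when its own 6 libraries were fitted alone. The common dispersion of these libraries was 0.0677, against 0.0175 to 0.0348 in the other 5 genotype and time pairs of that fit, so pooling likely understates their spread. Of the mock pairs, those with replicate 2 (by column number), the library without which the joint count was 1326, had a chi-square per degree of freedom of 57.2 and 56.1, and the pair without it 42.7. The joint count may therefore be too high, and the part of replicate 2 and of the smaller number of libraries in the separate fit stays open. No biological explanation was tested.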

How the results depend on the processing

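No processing alternative was chosen after results were seen. No paired analysis was possible for lsh1 at 72 h, or its difference from lsh1lsh2, because the mock titles skip a replicate number, and for overexpression the fit already held only the libraries compared. Where a cause is not given, the cause was not tested.

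With RLE size factors every count of called genes stayed within 1.5 times its value and 126 of 126 loci and lists kept direction and call. DESeq2 called 169 genes in lsh1 at 24 h (106 by edgeR), 187 in lsh1lsh2 at 24 h (60), and for the differences between lsh1lsh2 and lsh1 6 at 24 h (0, with 1084 at an unadjusted p under 0.05) and 1210 at 72 h (265), and between lsh1lsh2 and noot1noot2 2260 at 24 h (1015) and 786 at 72 h (380). Of the loci, 118 kept their call, 4 gained and 1 lost it. Without the filter, where more genes are tested, counts were 26 in lsh1lsh2 at 24 h, 84 for the lsh1 difference at 72 h and 416 for the noot1noot2 difference at 24 h, and 10 of 126 loci and lists lost their call. Fitting only the libraries compared, with fewer libraries to estimate the spread, gave 15 in lsh1 at 24 h, 146 in lsh1 at 72 h, 1470 in lsh1lsh2 at 72 h, 2 and 14 for the lsh1 differences at 24 and 72 h, and 155 for the noot1noot2 difference at 72 h, and 17 calls of loci were lost and 1 gained. In lsh1lsh2 at 24 h it called 78 genes, 8 of them among the 60. An estimated inter-gene correlation ended 12 of 37 list calls.

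The replicate number as a block gave 491 and 194 genes for the noot1noot2 differences at 24 and 72 h (1015 and 380), while the other counts stayed within 1.5 times (47 in lsh1lsh2 at 24 h, 1533 at 72 h). Of 29 pairs of equal numbers, 4 correlated above 0.1 (-0.14 to 0.16), so any pairing by number is weak. In noot1noot2 at 72 h, 3 of 3 libraries correlated best with their own number (0.06 to 0.11), against 0 of 3 in overexpression. The block ended the calls of ENOD11 (log2 12.19) and LBD16 (1.97) in lsh1 at 24 h, ENOD11 in lsh1lsh2 at 24 h (10.71), CRE1 (0.46), IPT3 (-0.54) and RR4 (0.67) in lsh1lsh2 at 72 h, and DNF1 (-0.41), CBS1 (-4.32) and EFD (-1.01) between lsh1lsh2 and noot1noot2. LSH2 in nf-ya1 at 24 h gained one (2.57).

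With each library left out in turn, counts ran from 20 to 266 in lsh1 at 24 h and 1326 to 7039 at 72 h, 10 to 78 in lsh1lsh2 at 24 h and 999 to 2975 at 72 h, and 3255 to 7084 in noot1noot2 at 24 h. For the differences they ran from 0 to 1 (lsh1, 24 h), 20 to 2665 (lsh1, 72 h), 5 to 2762 (noot1noot2, 24 h) and 72 to 803 (noot1noot2, 72 h), and for overexpression from 5528 to 10228. Within 1.5 times stayed noot1noot2 at 72 h (7328 to 10053) and nf-ya1 at 24 h (6730 to 8276) and 72 h (6435 to 8765). Over loci and libraries, 916 calls were unchanged, 121 lost and 6 gained. The difference of the LSH2 response between lsh1lsh2 and noot1noot2 at 72 h, not called (log2 -2.20), reversed without lsh1lsh2 mock replicate 3 (0.007), which held 7 of the 8 mock counts, and ran to -3.13 without lsh1lsh2 rhizobia replicate 3. Depth limits folds against uncounted mocks to lower bounds.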

Other observations

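The comparison of mock libraries between times, the overlaps and the correlation below were chosen after results had been seen, and the test against overexpression was not.

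Mock libraries at 72 h against mock libraries at 24 h were tested within each mutant. Of the 25 early symbiosis loci, 13 fell and 1 rose in lsh1, 12 and 1 in lsh1lsh2, 11 and 0 in noot1noot2, and 9 and 3 in nf-ya1. The list ranked below other genes by camera (adjusted p over the 4 mutants 0.000240, 0.00758, 0.000174 and 0.00518) but not with an estimated correlation (adjusted p = 0.288 to adjusted p = 0.342). DMI2, LYK3, NFP, NIN, PUB1 and RIP1 fell in all 4 mutants. NIN had a log2 of -1.86 in lsh1, -1.35 in lsh1lsh2, -2.34 in noot1noot2 and -1.45 in nf-ya1, and RIP1 of -4.87, -3.57, -3.01 and -3.76. Each time thus has its own mock level, which the responses at 24 and 72 h are measured against.

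Of 20397 genes tested in all 4 mutants, 29 rose in all 4 at 24 h and 0 fell by edgeR, and at 72 h 533 rose and 119 fell, with 4 and 25 listed loci among the risen. Of the 1409 genes that rose in lsh1lsh2 at 72 h, 1325 also rose in noot1noot2 at 72 h, where 270.7 would be shared by independent lists. The 2 responses share no libraries but share the estimate of spread. Across genes their log2 values correlated at 0.791 (Pearson). In lsh1lsh2 rhizobia 24 h replicate 2, NIN stood at 7.22 CPM, below the 10.75 to 16.41 CPM of the mock libraries of that mutant and time.

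A hypothesis tested here was that loci higher with LSH1LSH2 than with NOOT1NOOT2 overexpression would respond less to rhizobia at 72 h in lsh1lsh2 than in noot1noot2. Across 22433 genes, Spearman's rho was -0.039. Other splits of the 6 overexpression libraries, whose sign is arbitrary, reached an absolute value of 0.186, so the hypothesis was not borne out. Genes are not independent replicates, and the tissues differ.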
